A study of Mus musculus with 2 samples.

How the data were processed

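Cells of dissected, digested and triturated mouse optic nerve were captured with the 10x Genomics 3' droplet chemistry, version v2, and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The libraries were 1 from nerves 2 weeks after crush and 1 from uninjured nerves. Per the submitters' processing notes, the tools included bcl2fastq 2.17.1.14, Cell Ranger 1.3 and Seurat 4.0.3 and the genome build was mm10; the gene annotation release is not given in the sources used here. The authors deposited 1 table of whole-number UMI counts per gene and cell for both libraries, with a line that gives each cell's condition, and these counts are not normalized. Per the series' design text the authors kept 778 macrophages and microglia with at least 200 and at most 6500 genes. The table holds 778 cells, and no cell lay outside those limits. How cells were selected as macrophages or microglia is not given in the sources used here, and this selection sets the shares of other cell types.

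The table had 31053 gene rows, of which 14428 had at least 1 UMI. Of all rows, 26 carried names that a spreadsheet had turned into dates; they took 0.0506% of injured and 0.0754% of uninjured UMIs, stayed in the totals and were left out of the comparisons. Clec7a, a member of the list for disease-associated microglia, was not analysed here.

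The design set before the data were examined foresaw either summed counts or means per cell. Because the table holds counts, the main value is the sum of UMIs per library as CPM, counts scaled to a common library total, and the mean over cells with equal weight is the alternative. Ratios of summed counts carry exact conditional binomial intervals at 95%, levels exact Poisson and shares exact Clopper-Pearson intervals. A gene with 0 counts in a library is given as a bound against 3 counts over that library. Log2 ratios use a pseudocount of 10 CPM, which draws the ratios of scarce genes toward no difference. It lies under the 34.3 CPM that 0 uninjured UMIs allow, so genes with few or no uninjured UMIs can also be overstated. Genes compared were seen in at least 10% of the cells of one library, 4021 in all. List members had to be seen in at least 5%, with no minimum for markers of other cell types. A gene was called higher or lower at a ratio of 1.5 on the pseudocount scale. With 1 library per group no test was made.

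For 36 gene lists fixed before the data were examined, the median log2 ratio was set beside 10000 random lists of the same size matched on level in 20 bins, as a description of these libraries. Named genes followed a rule fixed at the same time. They are Fn1 and the measured fibronectin-binding integrins, the 15 genes with the highest and the 15 with the lowest log2 ratio without mitochondrial, ribosomal and predicted genes, up to 4 members of each list with the largest log2 ratio (up to 2 for other cell types), and the 5 leading genes of each cluster. Some further genes are named as exceptions, abundant members or leading genes in comparisons of cells, and were chosen after their values were seen. Some genes that the rule names are not reported here. The rule of size was tried on simulated counts with 200 genes changed by known folds among 4021 genes. It recovered 84% of genes raised 2-fold, 100% raised 4-fold, 68% lowered to 0.5 and 94% lowered to 0.25 of their level. The changed genes were drawn only from genes with at least 3 uninjured UMIs, so the recovery does not cover genes with fewer or none. Of the intervals, 98% held the true ratio. The counts were Poisson draws on library sums, the model behind the intervals. This coverage therefore says nothing about counts clumped in few cells.

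Cells were clustered on log-normalized counts of 2000 variable genes with 20 principal components, a graph of 15 nearest neighbours and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Other values were computed with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15. Positions are from GENCODE vM21, which uses the mm10 assembly. To compare shares of cells across depths, each cell was thinned to 500 UMIs, which left out 0 injured and 2 uninjured cells. No doublet caller was run on the 778 cells, and doublets were not removed. None of the 5 injured cells with T cell genes had a C1qa UMI, and 99 injured and 0 uninjured cells had over 15000 UMIs, so doublets among the deepest injured cells stay open. Cells were left out of alternatives only.

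The injured library had 42.3 times the UMIs of the uninjured one, so the precision of a ratio is set by the uninjured counts. In the injured library the deepest 73 cells held 56.2% of all UMIs, and in the uninjured library the deepest 5 cells held 44.9%, so that summed counts follow few cells. Mitochondrial genes took 2.75% and ribosomal protein genes 13.7% of injured UMIs, and 5.39% and 12.9% of uninjured UMIs. Alternatives tried were other pseudocounts, mean log values, equal weights, cells trimmed by genes seen, thinning, rescaling, other gene filters and ratios, and other settings of the clustering. Alternatives added after seeing the data left out the haemoglobin-rich cell, the cells with T cell genes, the uninjured cell with most Fn1, the clusters led by myelin genes or cells of 5000 UMIs or more, or looked within kinds of cell by depth and Malat1 share.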

Results

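Single-cell RNA was measured in macrophages and microglia of the mouse optic nerve, the tract that carries retinal axons to the brain. Wildtype 129S1/SvlmJ mice of both sexes had the nerve crushed at 8 weeks of age, and cells were taken 2 weeks later, at 10 weeks of age; uninjured nerves gave the control cells. There was 1 library per group, so differences between the groups have no replicate check and no test was made. Intervals are exact 95% intervals (Poisson for levels, Clopper-Pearson for shares) and cover counting error only. The injured library held 727 cells and 3697992 unique molecular identifiers (UMIs, each standing for 1 captured transcript). The uninjured library held 51 cells and 87499 UMIs. Median depth was 1123 UMIs per injured cell and 888 per uninjured cell, with ranges of 500 to 53972 and 458 to 11100. A count of 0 allows a level of up to 34.3 CPM, UMIs scaled to the same total in each library, in the uninjured library and 0.811 CPM in the injured library.

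The series is about fibronectin in the injured central nervous system, and the first comparison asked how much Fn1 RNA the immune cells of the nerve held. Fn1, which encodes the extracellular matrix protein fibronectin, lies on chromosome 1 from 71585520 to 71653200 on the minus strand of mm10 (protein-coding, GENCODE vM21 gene ENSMUSG00000026193.15). The injured library held 1114 CPM of Fn1 (1080 to 1148, 4118 UMIs) and the uninjured library 149 CPM (79.1 to 254, 13 UMIs), a level 7.495-fold higher after injury (4.38 to 14.1). Fn1 was seen in 382 injured cells, 52.5% of the library (48.8 to 56.2), and in 6 uninjured cells, 11.8% (4.44 to 23.9). With every cell thinned to 500 UMIs these shares were 29.2% of 727 injured cells (25.9 to 32.6) and 4.08% of 49 uninjured cells (0.498 to 14.0), and Fn1 UMIs per cell were 4.52-fold higher (1.92 to 14.0).

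As a measure of background, 5 injured cells carried at least 2 T cell receptor or Cd3 genes, and T cells are not a usual source of Fn1. These cells had 834 to 6332 UMIs, with a median of 5387, against 1123 in the whole injured library. None of them held an Fn1 UMI (0 to 52.2% of 5 cells), while Fn1 was seen in 77.8% of the 45 injured cells of 5000 to 15000 UMIs. A single uninjured cell held 7 of the 13 uninjured Fn1 UMIs. Without it the uninjured level was 69.7 CPM and the injured library 16.0-fold higher.

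**Figure D1:**
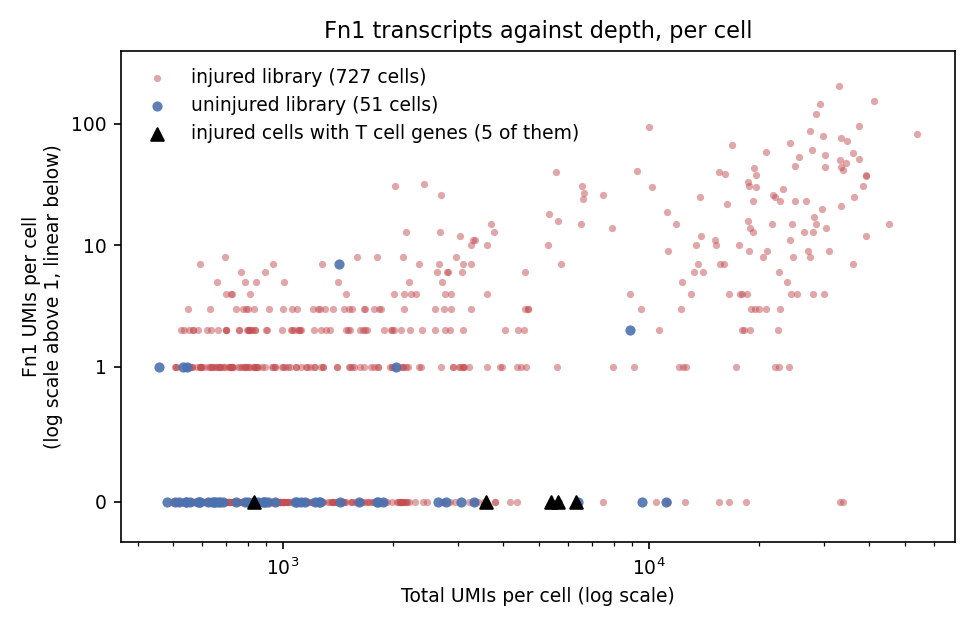
Fn1 UMIs per cell (vertical axis) against total UMIs per cell (horizontal axis), with 1 point per cell of the injured library, the uninjured library and the 5 injured cells with T cell genes. Injured cells over 15000 UMIs carried a median of 15 Fn1 UMIs, and 45 of the 51 uninjured cells carried none.

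Fn1 was carried by injured cells of all depths. The 99 cells over 15000 UMIs held 69.3% of the injured Fn1 UMIs, and 94.9% of them had at least 1. In cells under 600 UMIs the share was 22.9% in the injured (15.4 to 31.97) and 25% in the uninjured library (5.49 to 57.2, 3 of 12 cells), at 647 and 465 CPM, so no higher share was seen at this depth. From 600 to 1000 UMIs it was 37.6% of 218 injured cells and 0 of 17 uninjured cells (0 to 19.5). Cells were then divided, after the data had been seen, into deep cells of at least 5000 UMIs and into shallow cells rich or poor in Malat1, a nuclear RNA, with 1% of UMIs as the divide. Among deep cells Fn1 was at 1146 CPM in the injured library and 55.7 CPM in the uninjured one, 20.6-fold higher (5.69 to 170). Only 4 uninjured cells were deep, 1 of them rich in haemoglobin. That cell held 11100 of the 35936 uninjured deep UMIs, and 10194 of its UMIs were haemoglobin. It thus lowers the uninjured deep levels of most other genes and raises their ratios, here and in the deep values that follow. Among shallow Malat1-rich cells the levels were 1368 and 39.0 CPM, from 91 and 17 cells and with a single uninjured UMI. The ratio was 35.0 (6.23 to 1389). Median mitochondrial shares were 10.7% in these injured and 3.11% in these uninjured cells. Most of the 17 uninjured cells fell into cluster 7, described below, which held no injured cell. The cells of this kind were therefore not alike in the 2 libraries. Among shallow Malat1-poor cells they were 869 and 385 CPM, from 492 and 30 cells, a ratio of 2.25 (1.22 to 4.73), which became 7.10 (2.42 to 34.6) without the uninjured cell with most Fn1. Of the shallow cells, 59 injured and 1 uninjured lay between 0.5% and 2% Malat1, near the divide.

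**Figure D2:**
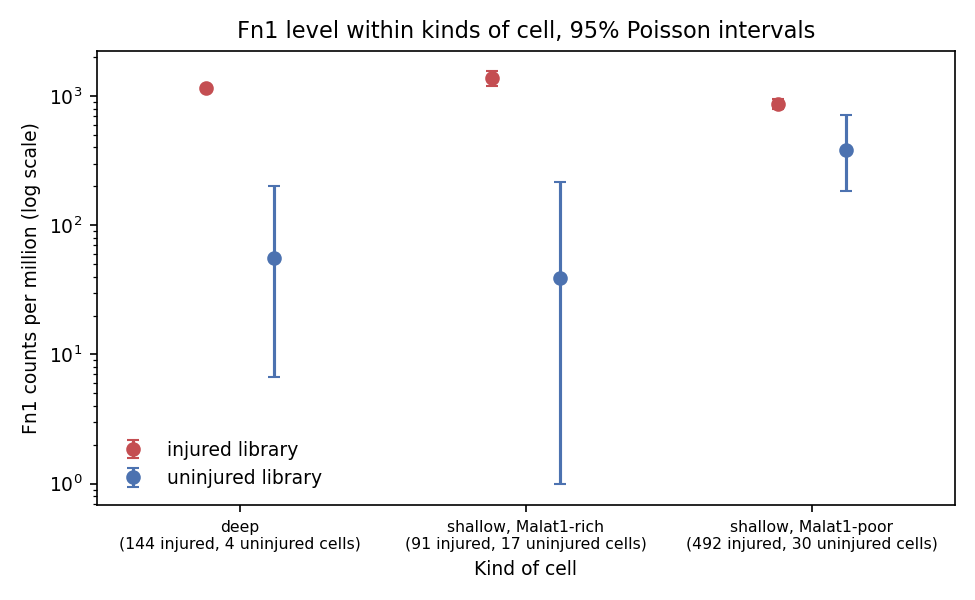
Fn1 level in CPM (log scale) within deep, shallow Malat1-rich and shallow Malat1-poor cells of each library, with 95% Poisson intervals as bars. The injured values of 1146, 1368 and 869 CPM lie above the uninjured values of 55.7, 39.0 and 385 CPM.

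Fibronectin is bound at the cell surface by integrins, and 5 of the 12 integrin subunits listed for this role were seen in enough cells to compare. Itgb1, the shared beta chain of the main fibronectin receptors, was higher in the injured library, at 344 CPM (325 to 363) against 91.4 CPM (39.5 to 180). Itga5, its classical fibronectin-binding partner, was scarce, with 85 injured UMIs and 1 uninjured UMI and a ratio of 2.01 (0.351 to 80.4). Itgav and Itga4 were lower after injury, by 3.29-fold (1.67 to 5.92) and 2.28-fold (1.02 to 4.43). By kind the counts were few. In deep cells Itgav had 110 injured and 0 uninjured UMIs. Its injured level of 37.3 CPM lies under the 83.5 CPM that 0 uninjured UMIs allow, so no direction can be read. In Malat1-rich cells Itga4 had a ratio of 1.89 (0.601 to 9.56). Itgb5 was at like levels, 758 and 743 CPM. The list as a whole had 2 members higher by at least 1.5-fold, 2 lower and 1 between, and its median log2 ratio was 0.03, at the 40.1 percentile of 10000 random lists matched on level. Within deep cells it was 1.60, with 4 higher and 1 lower, within Malat1-rich cells 0.86 and within Malat1-poor cells -0.11. Of the 4 higher in deep cells, Itga5 and Itgav had 0 uninjured UMIs and count as higher only through the pseudocount. The deep median is therefore uncertain. Of the members seen in fewer cells, Itga9, Itga2b, Itgb3, Itgb7 and Itgb8 had at most 36 UMIs in the injured library and 2 in the uninjured one, too few for a fold. Among other myeloid integrins 2 of 4 were higher and none lower. Itgax, a dendritic and activated-microglia subunit, had a ratio of 14.95 (2.67 to 592) on 1 uninjured UMI, and Itgb2 a ratio of 2.35 (1.19 to 5.46). The median of that list was 0.61 (88.7 percentile) and turned to -0.11 in cells under 5000 UMIs and to -0.48 in Malat1-rich cells.

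The next comparison asked which genes differed most in level between the libraries. Of the 15 genes highest in the injured library, 6 belong to the fixed list for lipid and cholesterol handling: Apoc1, Plin2, Lpl, Abcg1, Fabp5 and Abca1. Spp1, which encodes the secreted matrix protein osteopontin, was at 13120 CPM in the injured and 91.4 CPM in the uninjured library, 144-fold higher (72.8 to 332), and all 8 uninjured UMIs were in 1 cell. Gpnmb and Lgals3, glycoprotein and galectin genes of lipid-laden macrophages, and Igf1, a growth factor gene, had no uninjured UMI and were at least 36.5-fold, 30.3-fold and 14.5-fold higher. Abcg1, a cholesterol exporter, was at least 5.61-fold higher and Vat1 at least 5.36-fold. The lipoprotein genes Apoc1 and Apoc4 had ratios of 174 (48.1 to 1434) and 39.1 (7.01 to 1547), and the lipid droplet gene Plin2 one of 43.8 (7.86 to 1732). Lpl, which encodes lipoprotein lipase, had a ratio of 26.8 (9.15 to 130), the cholesterol exporter Abca1 one of 23.4 (6.46 to 193), and the fatty acid carrier Fabp5 was 20.7-fold higher (9.50 to 56.4). Cst7, Cxcl14 and Myo1e completed the set, with ratios of 36.8 (6.60 to 1456), 22.2 (9.49 to 68.3) and 25.6 (4.58 to 1010). Apoc4 lies beside other apolipoprotein genes whose transcripts overlap it, so its counts are uncertain.

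The genes lowest in the injured library were microglial, chemokine, stress and myelin genes. The microglial surface genes P2ry12 and Siglech were 14.2-fold (10.0 to 19.7) and 14.0-fold (9.57 to 20.04) lower, and Adgrg1 45.5-fold lower (19.8 to 105). The chemokine genes Ccl12 and Cxcl10 were 51.7-fold (41.5 to 64.5) and 12.0-fold (9.65 to 14.8) lower, and 150 of the 186 uninjured Ccl12 UMIs came from 2 cells; with cells weighted equally Ccl12 was at 34.1 CPM in injured and 632 CPM in uninjured cells. The heat shock gene Hspa1b was 17.6-fold lower (13.1 to 23.4); 66 of its 69 uninjured UMIs were in Malat1-rich cells, and in deep cells its ratio was 0.653 (0.220 to 3.20). Ccnd2, Csmd3, Col27a1 and Adamts1 were lower by 21.1-fold (13.3 to 33.0), 29.9-fold (15.1 to 58.1), 22.1-fold (12.6 to 37.9) and 12.8-fold (9.04 to 17.9); with equal weights Ccnd2 was at 29.5 and 192 CPM. The neural and myelin genes Kif5a, Mobp and Plekhb1 were lower by 107-fold (55.0 to 222), 12.2-fold (9.92 to 14.9) and 16.9-fold (9.21 to 29.8). With equal weights their levels were 18.4 and 704, 534 and 2487, and 47.4 and 359 CPM. Unc13c had no injured UMI and was at least 225-fold lower.

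By the fixed rule of size, 1317 of the 4021 genes compared were at least 1.5-fold higher in the injured library and 876 at least 1.5-fold lower. Counting noise alone, drawn 100 times from one common profile, gave a mean of 703 higher and 373 lower, so the shallow uninjured library leaves many calls of small size open. At 4-fold or more there were 224 higher and 90 lower genes, against 43.8 and 0.06 from counting noise. These draws were made on library sums and leave out that the UMIs of a gene can gather in few cells. Of the 186 uninjured Ccl12 UMIs, 150 were in 2 cells, so the gap to counting noise does not measure chance. The median log2 ratio over all compared genes was 0.17. With that shift removed the counts were 1091 and 1089, and without 1 uninjured cell in which 10194 of 11100 UMIs were haemoglobin they were 1134 and 1078.

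Gene lists fixed before the data were examined were then compared. Of the 19 measured genes that mark disease-associated microglia, 17 were higher, 1 lower and 1 between, with a median log2 ratio of 2.47 (2.12 to 2.53 from counting error). Apoe, the main lipid carrier of the nervous system, was 5.52-fold higher (5.24 to 5.82) and took 8.97% of injured and 1.62% of uninjured UMIs. Of the 1421 uninjured Apoe UMIs 1099 were in 2 deep cells, and without these the ratio was 19.2 (17.3 to 21.5). Trem2, a lipid-sensing receptor gene, was 2.69-fold higher (2.14 to 3.45) by sums and at 1796 and 1062 CPM with equal weights, while Axl was 1.65-fold lower (1.04 to 2.505). Of 14 measured genes of lipid and cholesterol handling 11 were higher and 2 lower, with a median of 3.37, or 2.48 with genes of 0 uninjured counts set at their bound. Of 18 lysosomal genes 13 were higher and none lower, with a median of 1.43, among them the protease genes Ctsb, 5.69-fold (4.74 to 6.88), and Ctsd, 4.42-fold (3.93 to 4.99), and Cd63, 7.52-fold (5.20 to 11.3). Of 14 glycolytic genes 12 were higher, with a median of 1.56. Gapdh was 5.19-fold higher (3.57 to 7.89) and Pkm 7.28-fold (3.69 to 16.9), while Hk2 was 4.08-fold lower (3.13 to 5.24). All 4 medians lay above those of 10000 matched random lists. Within deep, Malat1-rich and Malat1-poor cells the disease-associated median was 2.92, 2.21 and 2.35. The lipid median was 3.70, 3.28 and 3.34, and the lysosomal median 2.06, 0.40 and 1.07. A count of 0 allows an uninjured level of 83.5, 117 and 116 CPM in these kinds, far above the pseudocount of 10 CPM. Abcg1, Gpnmb and Igf1 had 0 uninjured UMIs in each kind, and only 4 uninjured cells were deep, 1 of them rich in haemoglobin. The size of these medians is therefore uncertain.

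**Figure D3:**
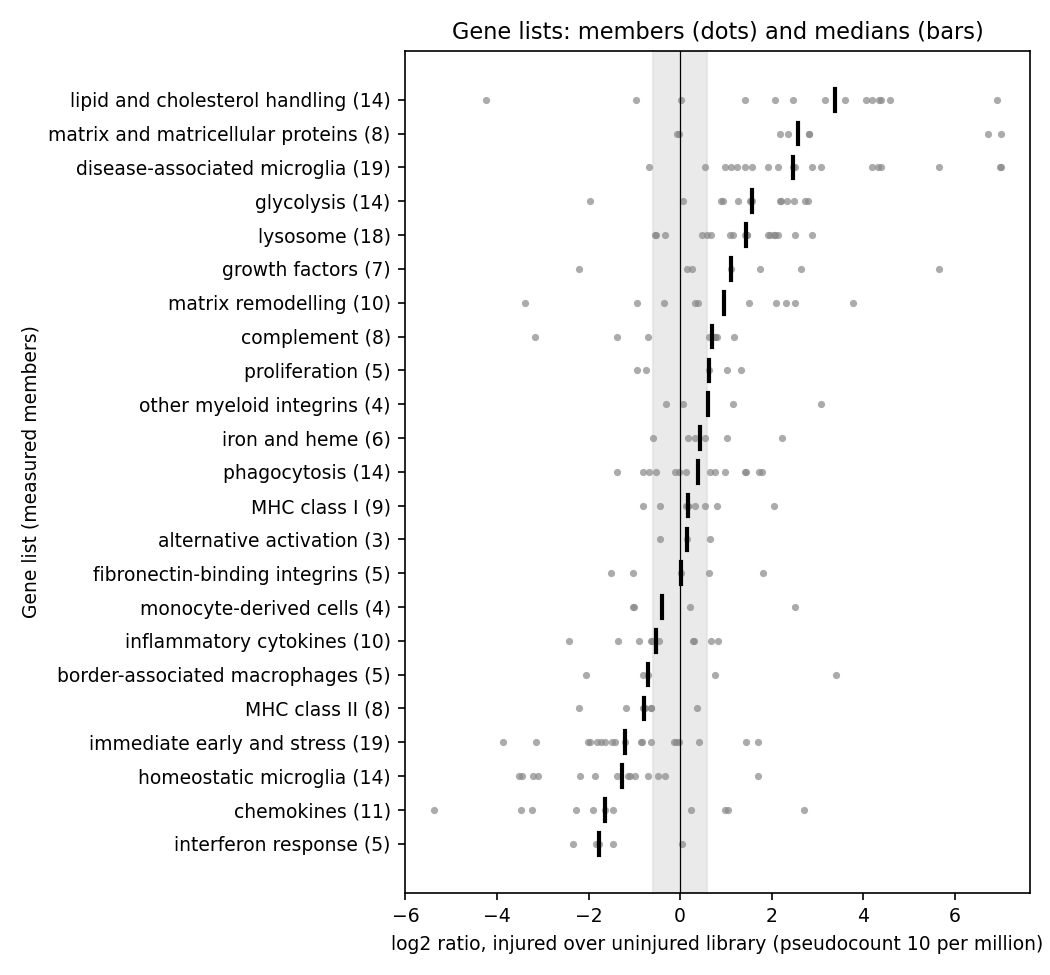
log2 ratio of injured over uninjured CPM (pseudocount 10 CPM) for each measured member (dots) and the median (bars) of the 23 lists that were not markers of other cell types; the shaded band spans ratios under 1.5-fold. Lipid handling has the highest median, 3.37, and the interferon response the lowest, -1.78.

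Matrix genes were also higher. Of 8 measured matrix and matricellular genes 6 were higher and none lower, with a median of 2.58, above the random lists, or 1.49 with bounds. They included Spp1, Lgals3, Fn1 and Ecm1, the last at least 1.75-fold higher, while Sparc was at 1094 and 1109 CPM. Of 10 matrix remodelling genes 5 were higher and 2 lower, with a median of 0.95 (99.8 percentile), or 0.42 with bounds. The elastase gene Mmp12 was at least 3.71-fold higher, though seen in only 5.36% of injured cells, and Adam8 at least 1.36-fold; Plau had a ratio of 6.67 (1.84 to 55.2), and the protease gene Adamts1 was lower. Of 7 growth factor genes 4 were higher and 1 lower, with a median of 1.12 (99.1 percentile), or 0.61 with bounds. The median was 2.71 in deep, 0.24 in Malat1-rich and 1.16 in Malat1-poor cells. Vegfa was at least 1.52-fold higher and Pdgfa had a ratio of 4.37 (1.20 to 36.2), while Pdgfb was 5.31-fold lower (3.35 to 8.07).

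Genes of homeostatic microglia were lower in the injured library. Of 14 measured members 11 were lower, 1 higher and 2 between, with a median of -1.27 (-1.58 to -1.04), at the 0.03 percentile of random lists. Besides P2ry12 and Siglech, the membrane protein gene Tmem119 was 11.1-fold (7.82 to 15.5) and the receptor gene P2ry13 12.8-fold (7.35 to 21.4) lower. Fcrls went the other way, with a ratio of 3.94 (1.34 to 19.1). After thinning, Tmem119 was seen in 1.38% of injured cells (0.662 to 2.52) and 24.5% of uninjured cells (13.3 to 38.9), and without thinning in 9.77% and 43.1%. The list's median was -0.18 in deep cells, -2.41 in Malat1-rich and -0.95 in Malat1-poor cells, beside medians over all compared genes of 0.58, 0.02 and 0.49. In deep cells P2ry12, Siglech and Tmem119 had ratios of 0.103 (0.0588 to 0.193), 0.0800 (0.0453 to 0.152) and 0.225 (0.111 to 0.531).

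Immediate early and stress genes, which also respond to cell dissociation, were lower in the injured library in 13 of 19 cases and higher in 2, with a median of -1.21, below the random lists. Hspa1a was 9.57-fold lower (7.57 to 12.0), Klf2 4.14-fold (3.35 to 5.08) and Socs3 3.95-fold (3.35 to 4.64). Hspa1a and Hspa1b are nearly identical in sequence, so the division of counts between them is uncertain. Malat1-rich cells held 89 of the 94 uninjured Hspa1a UMIs. In deep cells, where the haemoglobin-rich cell raises the ratios of most genes, the ratio was 0.978 (0.416 to 3.03). The list had a median of -0.66 in deep, -1.69 in Malat1-rich and -0.17 in Malat1-poor cells. Of 11 chemokine genes 7 were lower and 3 higher, with a median of -1.65, below the random lists; it was -0.45 with each cell weighted equally and -0.35 in cells under 5000 UMIs, and turned to 0.23 in Malat1-poor cells. Ccl4 was 9.60-fold lower (8.55 to 10.7), while Cxcl1 had a ratio of 8.94 (2.47 to 74.0). Of 5 interferon response genes 4 were lower and none higher, with a median of -1.78 (0.13 percentile), and Ifitm3 was 5.59-fold lower (3.93 to 7.76), Ifi27l2a 3.86-fold and Xaf1 3.99-fold. Of 10 inflammatory cytokine genes 5 were lower and 2 higher, with a median of -0.54 (6.99 percentile). In Malat1-poor cells it turned to 1.00, with 7 higher and 1 lower and with 142 injured and 0 uninjured UMIs of Il1b, while it was -0.89 in deep and -0.72 in Malat1-rich cells. Il1a was 5.68-fold lower (4.36 to 7.32), Il1b 1.87-fold (1.59 to 2.19) and Tlr2 2.63-fold. With equal weights Il1b was at 623 and 739 CPM, and it was seen in 24.5% of injured and 15.7% of uninjured cells, while Nlrp3 had a ratio of 1.89 (0.860 to 5.16) that turned with equal weights, at 91.1 and 102 CPM.

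The remaining immune lists were mixed. Of 8 MHC class II genes 7 were lower and none higher, with a median of -0.78 (1.16 percentile). However, 2 deep uninjured cells held 90.5% of the 704 uninjured UMIs of that list, and the median was 0.40 with each cell weighted equally, -1.73 in deep, 1.70 in Malat1-rich and 0.53 in Malat1-poor cells. Cd74 was 1.74-fold lower (1.56 to 1.94) by summed counts and yet was seen in 35.9% of injured and 15.7% of uninjured cells; H2-Ab1 was 1.77-fold lower (1.45 to 2.15), but higher with equal weights, at 553 and 254 CPM. H2-DMa was 2.35-fold and H2-Oa 7.18-fold lower. Of 9 MHC class I genes 2 were higher and 1 lower, with a median of 0.17 (56.9 percentile); Psmb8 had a ratio of 1.79 (1.06 to 3.29) and H2-D1 one of 1.46. Of 8 complement genes 5 were higher and 3 lower, with a median of 0.69 (94.2 percentile) that was 0.02 in cells under 5000 UMIs and turned to -0.49 in Malat1-rich cells. C1qa was 1.55-fold (1.41 to 1.71) and C3ar1 2.43-fold higher, while C4b was 12.2-fold lower (7.57 to 19.1). However, 21 of the 26 uninjured C4b UMIs were in the 4 deep cells, the levels with equal weights were 83.0 and 164 CPM, and the gene was seen in 10.2% of injured and 7.84% of uninjured cells. Of 14 phagocytosis genes 7 were higher and 3 lower, with a median of 0.40 (85.5 percentile), or 0.05 with bounds, and Cd68 was 3.38-fold higher (2.25 to 5.34) by sums and at 702 and 334 CPM with equal weights. Of 6 iron and heme genes 2 were higher and 1 lower, with a median of 0.42 (82.1 percentile). Ftl1, a ferritin chain gene, was 4.67-fold higher (4.04 to 5.42). Border-associated macrophage genes had 2 of 5 higher and 3 lower, with a median of -0.70 (14.4 percentile) that turned to 0.04 with cells weighted equally and to 1.94 in Malat1-rich and 1.46 in Malat1-poor cells. Ms4a7 had a ratio of 14.8 (4.08 to 122) and Folr2 was 5.07-fold lower (2.76 to 8.69). All 15 uninjured Folr2 UMIs were in 2 cells, the levels with equal weights were 27.8 and 44.8 CPM, and the gene was seen in 9.49% of injured and 3.92% of uninjured cells. Monocyte-derived genes had 1 of 4 higher, Lyz2 at 5.70-fold (4.98 to 6.55), 2 lower and a median of -0.40 (25.6 percentile), which was 1.03 in deep, 1.63 in Malat1-rich and -1.20 in Malat1-poor cells. Proliferation genes had 3 of 5 higher and 2 lower, with a median of 0.63 (91.4 percentile) that turned to -0.44 after thinning and to -0.86 in Malat1-rich cells. Alternative activation genes had 1 of 3 higher, Msr1, and a median of 0.15 (61.6 percentile).

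Markers of other cell types were measured beside these lists. Of 10 oligodendrocyte genes 9 were lower in the injured library and 1 higher, with a median of -2.49, below the random lists. It was -1.07 with equal weights and -1.16, -1.30 and -1.66 in deep, Malat1-rich and Malat1-poor cells. Mbp, a major myelin protein gene, was at 699 CPM in the injured library and 4994 CPM in the uninjured library (2953 and 8085 CPM with equal weights), and was seen in 63.8% and 98.0% of cells. The erythrocyte list was lower in all 5 cases, with a median of -10.15, and 10194 of its 10217 uninjured UMIs were in the single haemoglobin-rich cell. Of 10 astrocyte genes 5 were lower and 1 higher, with a median of -0.74 (0.08 percentile) that turned to 0.05 with equal weights and was 0.14, 0 and 0.10 within deep, Malat1-rich and Malat1-poor cells. Slc1a3, which microglia can also express, was 7.27-fold lower (5.72 to 9.14). Malat1-rich cells held 83 of its 87 uninjured UMIs, and in deep and Malat1-poor cells its ratios were 1.57 (0.535 to 7.67) and 2.37 (0.407 to 95.5). No other list had a median beyond 1.5-fold. Medians were 0.38 for 7 oligodendrocyte precursor, 0.25 for 7 endothelial, 0.06 for 4 mural, 0.04 for 7 fibroblast, 0.04 for 7 neutrophil, 0.31 for 12 T and NK cell, 0.04 for 4 B cell, 0.18 for 7 dendritic cell, 0.18 for 1 mast cell and 0.06 for 2 neuron genes. Most members of these lists had too few UMIs for a fold. Cspg4, which had no uninjured UMI, was at least 2.22-fold higher, and Ighm was 3.34-fold lower (1.49 to 6.56).

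Clustering asked which cell classes the libraries held, and gave 7 clusters that divided mostly by depth, RNA makeup and library. Cluster 7 held 16 uninjured cells, 31.4% of that library (19.1 to 45.9), and no injured cell. This depends on the setting: at resolution 0.25, with 4 principal components and with all genes, 16, 12 and 13 of these cells fell into clusters with 102, 104 and 97 injured cells. The cluster was called microglia-like, since 9 microglial markers were detected and P2ry12 and Siglech stood among its top 10 genes by fold. These genes were led by the stress gene Hspa1b with Csmd3, Col27a1 and Adamts1. The count of detected markers does not set the cluster apart, as 10 were detected in the injured cells of cluster 2 and 7 in cluster 6. A cluster of cells from 1 library may reflect that library and not a cell type, so its size is not compared between the groups. Clusters 1, 3 and 5 were led by myelin genes such as Mbp, Mobp, Cldn11 and Mal. In clusters 1 and 3 oligodendrocyte genes took 0.662% and 0.539% of UMIs and the C1q genes of macrophages and microglia took more, 2.39% and 0.642%. In cluster 5 oligodendrocyte genes took 2.62% and C1q genes 1.12%. With RNA of both cell types in each, all 3 stayed unnamed. Cluster 5 was the one with most cells of both libraries, 9 injured and 29 uninjured. There Fn1 was at 324 CPM (3 UMIs) in injured and 397 CPM (10 UMIs) in uninjured cells, a ratio of 0.816 (0.144 to 3.17), so that a difference was not detectable at this depth. Cluster 6, with 29 injured and 3 uninjured cells and the leading genes Ccl7, H2-Eb1, H2-Aa, Ccl2 and H2-Ab1, had an Fn1 ratio of 4.50 (1.21 to 37.8) on 2 uninjured UMIs. Cluster 2 held 133 injured cells with a median of 19613 UMIs and the leading genes Cxcl1, Hist1h2ap, Gem, Hist1h2ae and Tnf. Cluster 4 held 98 injured and 2 uninjured cells, had a median ribosomal protein share of 2.68% and was led by Vps37b, Nabp1, Ifi203, Ahnak and Pde1b. Fn1 in the injured library was at 1169 CPM in cluster 2, 1666 CPM in cluster 4, 992 CPM in cluster 1, 470 CPM in cluster 6 and 203 CPM in cluster 3.

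**Figure D4:**
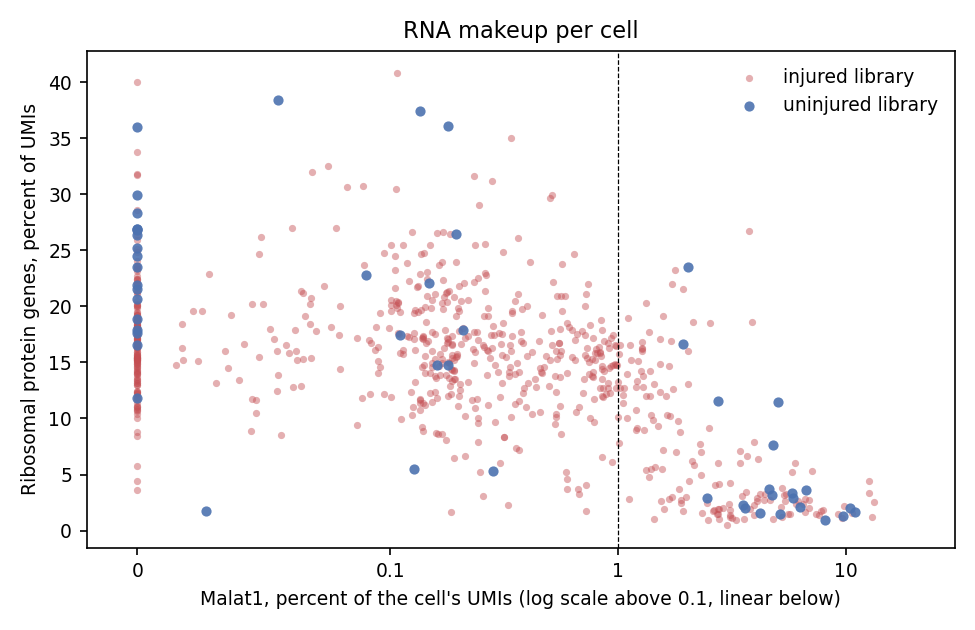
Share of each cell's UMIs from ribosomal protein genes (vertical axis) against the share from Malat1 (horizontal axis, dashed line at 1%), with 1 point per cell of each library. Of the shallow cells, 91 injured and 17 uninjured ones lie at or above 1% Malat1, and 492 and 30 lie below.

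Within the injured library, cells in which Fn1 was seen were compared with the others after thinning to 500 UMIs. In the 212 cells with an Fn1 UMI, Spp1 was 2.15-fold higher (2.01 to 2.30), Cd83, an activation marker gene, 1.97-fold (1.39 to 2.77), Lpl 1.91-fold (1.499 to 2.43), the tetraspanin gene Cd9 1.72-fold (1.47 to 2.01) and Sparc, a matricellular gene, 1.62-fold (1.30 to 2.02) than in the 515 others. Lgals3 was 1.63-fold (1.23 to 2.18) and Fabp5 1.54-fold (1.21 to 1.97) lower in the cells with Fn1, as was Mbp by 1.65-fold (1.42 to 1.93). The 2 sets mix clusters in different shares, since Fn1 was seen in 93.2% of the injured cells of cluster 2 and 15.7% of those of cluster 3, where Spp1 took 1.49% and 0.173% of UMIs. Cells of a library are not replicates, so these values describe this library.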

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

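All alternatives that left out single cells, the myelin-led clusters or deep cells, and those within kinds of cell, were chosen only after the results were seen. No paired analysis was possible because there was 1 library per group. Leaving out clusters named after a non-myeloid type, as set beforehand, was not run, since no cluster had such a name; the 3 clusters led by myelin genes were left out instead. The log2 ratio of Fn1 (2.82) stayed positive under the 12 alternatives. Other pseudocounts and leaving out the uninjured cell with most Fn1 could not have changed its sign. The ratio was 1.51 as a difference of mean log values, 2.05 with equal weights and 1.85 without the cells with fewest and most genes (outer cells). It was 2.12 thinned, 4.10 without myelin-led clusters and 2.16 in cells under 5000 UMIs. Within cluster 5 it was -0.29 and, at resolution 1, -5.35 with 0 and 10 UMIs. The latter size is set by the pseudocount, as there were only 4 injured cells and the ratio had bounds of 0 and 3.21. The log2 ratio was 4.14 in deep and 4.81 in Malat1-rich cells. In Malat1-poor cells it was 1.15, or 2.73 without the uninjured cell with most Fn1. The share of injured cells with Fn1 was 29.2% thinned against 52.5%. Higher and lower genes numbered 397 and 354 with a pseudocount of 1 per 10000, 214 and 77 by mean log values, 2982 and 3101 with all genes, 406 and 156 at a 25% filter, and 786 and 462 at a ratio of 2, the last 3 by their own construction. None of the 6 lists led with was reversed under 12 alternatives, though other pseudocounts keep the sign of every gene. In the order pseudocount of 1 per 10000, mean log values, equal weights, outer cells left out, thinned, no myelin-led clusters and cells under 5000 UMIs, the homeostatic median was -0.89, -0.60, -1.78, -2.32, -1.60, -1.79 and -2.08. The disease-associated median was 2.11 with that pseudocount, 1.42 by mean log values, 2.70 thinned, 2.03 without myelin-led clusters and 2.75 under 5000 UMIs. The lysosomal median was 0.97 by mean log values, 0.92 with equal weights, 0.98 without outer cells, 0.96 thinned and 0.83 under 5000 UMIs. The lipid median was 4.11 and 1.44 with pseudocounts of 0.01 and 1 per 10000 and 1.00 by mean log values, and the glycolytic one 1.02 with 1 per 10000 and 0.73 by mean log values. The immediate early and stress median was -0.46 by mean log values, -1.99 without outer cells, -1.67 without myelin-led clusters and -1.65 under 5000 UMIs. Of 17 other lists 10 had a median beyond 1.5-fold, and 4 of these were reversed. They were other myeloid integrins (-0.17 without outer cells, -0.11 under 5000 UMIs), border-associated macrophages (0.0374 with equal weights, 2.43 thinned, 0.41 under 5000 UMIs), MHC class II (0.11 by mean log values, 0.40 with equal weights, 2.32 without outer cells, 0.20 thinned, 0.87 under 5000 UMIs) and proliferation (-0.31 without outer cells, -0.44 thinned, -0.21 under 5000 UMIs). Of the lists that kept their direction under these 12 alternatives (chemokines and complement turned within 1 kind of cell), matrix (2.58) was 0.71 with a pseudocount of 1 per 10000 and 0.22 by mean log values, interferon response (-1.78) -0.82 and -0.27, growth factors (1.12) 0.47 and 0.18, matrix remodelling (0.95) 0.39 and 0.16, chemokines (-1.65) -1.002 and -0.11, and complement (0.69) 0.41 and 0.19, with 0.02 in cells under 5000 UMIs. The cause of these shifts was not tested. The microglia-like cluster kept its 16 cells at resolution 1 and with 10 principal components, with 0 injured cells. At resolution 0.25, with 4 components and with all genes, 16, 12 and 13 of them fell into clusters with 102, 104 and 97 injured cells and no microglial marker in the top 10, so the absence of injured cells held in 2 of these 5 settings. The uninjured library's 87499 UMIs limit the scarce genes.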

Other observations

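The division of deep injured cells by Fn1 and all tests of explanations below were chosen only after the results were seen. Among injured cells of at least 5000 UMIs without T cell genes, the 70 cells with the greater Fn1 share (1980 CPM, median 20258 UMIs) were set beside the 70 with the lesser share (242 CPM, median 18626 UMIs). The genes named here are taken from those with the greatest differences, and no gene list was tested. Tnf, a cytokine gene, was 26.4-fold higher (16.3 to 45.6) and seen in 28 against 8 cells, and the neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 were 10.9-fold and 4.33-fold higher, seen in 26 against 9 and 33 against 15 cells. In the cells with less Fn1, 1 cell held 47.1% of the Tnf, 37.5% of the Cxcl1 and 44.3% of the Cxcl2 UMIs. Lpl was 3.60-fold higher (3.27 to 3.95), with median levels per cell of 1109 and 117 CPM, and the chemokine gene Ccl6 was 4.09-fold higher, seen in 52 against 38 cells. By sums the antigen presentation genes H2-Aa, H2-Eb1, H2-Ab1 and Cd74 were 3.79-fold, 3.33-fold, 3.11-fold and 2.82-fold lower. H2-Aa and H2-Eb1 were seen in 17 against 26 and 18 against 26 cells, but H2-Ab1 in 43 against 40 and Cd74 in 57 against 53 cells. Medians per cell were 47.7 and 59.6 CPM for H2-Ab1 and 178 and 187 CPM for Cd74. Gpnmb was 2.17-fold lower by sums, yet seen in 62 against 56 cells. The 2 sets were not matched by cluster. H2-Eb1, H2-Aa and H2-Ab1 were among the leading genes of cluster 6, where injured Fn1 was at 470 CPM against 1169 CPM in cluster 2. Another mix of clusters therefore stays open. The cells of both sets are from 1 library and not replicates.

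For the higher Fn1 of the injured library, free RNA as the whole source does not match the 0 Fn1 UMIs in cells with T cell genes, whose upper bound is 0.738 per cell against 5.70 in other injured cells. In injured cells under 1000 UMIs there were 0.615 Fn1 UMIs per cell, under that bound. If free RNA carried Fn1 and Apoe in the ratio of the other cells, the Apoe in cells with T cell genes would bring 0.0571. Not all other genes kept to such a ratio. Lgals3 and Mbp lay above it, at 1 and 1.4 UMIs per cell against 0.0532 and 0.0358. Spp1 and Lyz2 were at 0.2 (up to 1.11) and 0 (up to 0.738) against 0.673 and 0.711. These 2 expected values lie within counting error, so no departure is shown for them. Free RNA as a source of Fn1 in the shallow cells was thus not settled. Thinning to equal UMI numbers left Fn1 UMIs per cell 4.52-fold higher (1.92 to 14.0). That interval covers counting error only and rests on 5 uninjured Fn1 UMIs in 4.08% of 49 cells. Thinning also keeps the deep injured cells. In cells under 600 UMIs the levels were 647 and 465 CPM with no higher share, so cell traits that go with depth stay open. Another mix of deep, Malat1-rich and Malat1-poor cells does not account for the higher Fn1 by sums. The injured levels of each kind predict 98.7 uninjured Fn1 UMIs, 7.59 times (4.44 to 14.3) the 13 counted. This prediction counts the UMIs of the haemoglobin-rich cell, which raises it. The shallow kinds also held cells of unlike mitochondrial share in the 2 libraries, so differences within a kind stay open. Another mix of cell types cannot be told apart from a difference within a type, because the microglia-like cluster held 0 injured cells, and at resolution 0.25, with 4 components or with all genes its cells shared a cluster with 102, 104 or 97 injured cells and no class was named. A response to injury and a difference between 2 single preparations both stay open.

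Mbp, a myelin gene, was seen in 63.8% of injured and 98.0% of uninjured cells that the authors took for macrophages or microglia. If cells made it in proportion to their own RNA, Mbp UMIs per cell would follow depth, but between injured cells under 600 and over 15000 UMIs they were only 1.60-fold higher (0.970 to 2.89) while total UMIs were 46.2-fold higher. If free RNA were shared evenly among droplets, the variance over the mean in the 327 injured cells under 1000 UMIs would be near 1.13, but it was 17.6 (10.9 to 23.6), and the 10% of these cells with most Mbp held 67.0% of their Mbp UMIs. Pieces of myelin carried with or inside cells, and doublets, could give such uneven counts and were not tested.

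Shallow Malat1-poor cells made up 67.7% of injured and 58.8% of uninjured cells. Empty droplets with only evenly shared free RNA do not match injured cells under 1000 UMIs. These held 41.8 Apoe UMIs per cell, against 4.60 (up to 6.90) in the 5 injured cells with T cell genes. The 41.8 was taken over all injured cells under 1000 UMIs and not over Malat1-poor cells alone. Free RNA shared unevenly was not tested. A single kind of damage shared by both libraries does not match the Malat1-poor cells. Their median mitochondrial shares were 0.503% in the injured and 8.11% in the uninjured library. What these cells are could not be settled, and values by sums rest mainly on the deep injured cells.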
